A study of Mus musculus with 4 samples.

How the data were processed

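Nuclei were isolated from the cortex of 5-month-old wildtype and Setdb1-CK-cKO mice (a conditional knockout of Setdb1, whose CK part the labels do not explain), with 2 animals per genotype and 1 10x 3′ library per animal. Setdb1 encodes a methyltransferase of histone H3 lysine 9. The deposited matrices hold raw UMI counts per gene and barcode, made by the authors with Cell Ranger 7.1.0 on mm10 per the submitters' processing notes, with no normalization. Whether intronic reads were included, whether strand was used in counting and whether free RNA was removed are not given in the sources used here. Each matrix lists 32285 genes. The libraries held 14493, 14365, 11790 and 13902 barcodes and 45605971, 42780840, 38503740 and 38314394 UMIs (wildtype replicates 1 and 2, knockout replicates 1 and 2). Median UMIs per barcode were 2743, 2675, 2903.5 and 2468.5, and the lowest total was 500 or 501, so the barcodes had been filtered before deposit. Sequence reads and behaviour of the animals were not analysed here.

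Nuclei with at least 500 UMIs, 300 detected genes and at most 5% mitochondrial UMIs were kept. Scrublet, as part of scanpy 1.11.5 under Python 3.11.15, marked doublets per library at an expected rate of 10% and its automatic threshold (4.14% to 5.11% of nuclei), and 2464 doublets were removed. For clustering, counts were scaled to 10000 per nucleus and logged, and 2000 variable genes were chosen within libraries without Setdb1, Xist, Tsix, Y-linked and mitochondrial genes. Clusters came from 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 1.0, with random seed 1 and no integration of libraries. Of 32 clusters 23 were named from marker lists set before the data were examined, by the markers detected in at least 5% of their nuclei and by their 10 leading genes. The other 9 were left unnamed, because markers of different classes were both present, too few markers were found, or housekeeping and ribosomal genes led. Clusters of neurons were named by subclass where 1 subclass led, and otherwise kept their number. Shares of nuclei have exact Clopper-Pearson 95% intervals and shares of UMIs Wilson 95% intervals, and these cover counting error only.

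UMI counts were summed per library and class, so the animal is the unit of replication. A class or subclass was tested where every library had at least 30 nuclei, which gave 10 classes and 14 subclasses or numbered clusters of neuron-like nuclei, the unnamed cluster 28 among them. Genes were filtered with filterByExpr by genotype (minimum count 10), scaled with TMM factors and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, genotype alone in the design) under R 4.3.3, with Benjamini-Hochberg adjustment within the class and a threshold of 0.05. The standard error is the absolute log2 fold change over the square root of F. Class shares were tested with edgeR quasi-likelihood on nuclei per class, the library total of named nuclei as offset. The difference of effects between excitatory neurons and another class was the genotype by class term beside a library term. Gene lists, 28 set before the data were examined and 31 marker lists, were tested with camera from limma 3.58.1 at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, adjusted within each class and family of lists, where at least 3 members were tested. Symbols made of Gm plus digits, ending in Rik or starting with a clone name count as predicted, and their share was tested with Fisher's exact test, in which genes are not independent.

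Genes were named by rule. In excitatory neurons these were the 10 highest and 10 lowest log2 fold changes among established symbols and the 4 highest and 4 lowest among predicted ones, given adjusted p under 0.05, at least 5 CPM in 1 genotype and both knockout libraries on the same side of both wildtype libraries. In other classes the 6 highest and 6 lowest established symbols were named by the same rule, and from each list up to 4 members with the smallest p. Where fewer than 5 genes passed in a class, all that passed and those with the 5 smallest p apply. Where the wildtype libraries of a class had 0 UMIs of a named gene, the change is given as at least the fold that 3 wildtype UMIs would give. Where they had 1 to 3, the ratio of summed CPM is given with its exact 95% counting interval.

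Annotation was read from GENCODE vM21 (GRCm38). Of the 32285 gene identifiers 32235 (99.8%) were found there, and 97.7% had the same symbol. Strand overlaps, chromosomes and biotypes come from it, and the authors' annotation may differ.

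The tests of genes and lists were also tried on simulated data with the means, library sizes and spread of each class. edgeR found 77.3% of genes changed by 1 log2 unit and 21.2% of those changed by 0.5 in excitatory neurons (19059 genes, 24 false calls). At 1 log2 unit it found 80.3% in inhibitory neurons (14432 genes, 5 false calls), 41.9% in astrocytes (12181 genes, 17 false calls), 73.1% in oligodendrocytes (12299 genes, 12 false calls), 48.5% in oligodendrocyte precursors (9109 genes, 12 false calls) and 58.3% in microglia (8983 genes, 9 false calls). False calls were a larger share of the edgeR calls than the adjusted p threshold in each of these classes except inhibitory neurons. In the same order of classes, DESeq2 made 5, 0, 2, 1, 1 and 0 false calls on these data. Those of limma-voom were 22, 4, 14, 10, 10 and 7. The share of changed genes found by these other methods is not given here. The test of differing effects found 82.5% of 200 genes that differed by 1 among 9200, with 16 false calls, again a larger share than the threshold. Camera called 0 of 28 lists with none raised and 1 with 1 raised. Genes were drawn independently there, so this does not check camera where the genes of a list move together. Camera with an estimated correlation and fry were not tried there. Whether they could call a changed list with n = 2 per genotype is therefore not known. The share test found a 1.5-fold rise of microglia in 19 of 20 draws, with 5 false calls. In these draws the spread between libraries was set to the same value for every class and not taken from the data. The result does not cover classes whose shares vary more.

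Alternatives chosen before the data were examined were DESeq2 1.42.0, upper-quartile factors, no low-count filter, limma-voom, replicate number as a block, listed sex as a covariate, each library left out, doublets kept, nuclei of at least 1000 UMIs, resolution 2.0 and equal nuclei per library. For single results they also included equal nuclei of both classes, other denominators of shares, equal class shares and an expression-matched background. After the data were seen, astrocytes of cluster 12 alone and excitatory neurons without ribosomal protein and mitochondrially encoded genes were added. The listed sex of both knockout animals is opposite to their sex-linked RNA, so listed sex as a covariate does not group the libraries by sex-linked RNA, and replicate number as a block does. Genotype groups were taken from the labels. Log2 values are printed to 2 decimals and other values to 3 digits, with 1 more digit where the rounded value would equal an unrelated setting typed in the code. Results for some single genes are not reported here.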

Results

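After filtering, 52038 nuclei were kept from 4 mouse cortex libraries: 13882 and 13712 from wildtype animals (replicates 1 and 2), and 11176 and 13268 from Setdb1-CK-cKO animals. Of these, 46007 fell in 11 named classes. Excitatory neurons were the largest class (6602, 7103, 5682 and 7101 nuclei in the same order of libraries). Oligodendrocytes (1896, 1935, 1355, 1315), inhibitory neurons (1115, 1287, 942, 1250), astrocytes (1049, 1022, 668, 847), microglia (550, 579, 522, 646) and oligodendrocyte precursors (338, 389, 298, 398) followed. Counts were summed per library and class, so every comparison has n = 2 animals per genotype. Effects are log2 fold changes, knockout over wildtype, ± standard error from edgeR quasi-likelihood fits. Adjusted p values are Benjamini-Hochberg values over all genes tested in the class, with 0.05 as the threshold, and levels are means of CPM, UMI counts scaled to a common library total with TMM factors. In simulated data the share of false edgeR calls exceeded this threshold in every class tried except inhibitory neurons. The numbers of genes called by edgeR may therefore hold more false calls than the threshold states.

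Setdb1 RNA did not pass in any class. In excitatory neurons Setdb1 (ENSMUSG00000015697) measured 70.3 CPM in wildtype and 68.9 CPM in knockout (log2 fold change -0.03 ± 0.0855, edgeR adjusted p = 0.875, n = 2 per genotype). Its log2 fold change was 0.01 ± 0.113 in inhibitory neurons, 0.19 ± 0.243 in astrocytes, 0.08 ± 0.172 in oligodendrocytes, 0.22 ± 0.282 in oligodendrocyte precursors and -0.27 ± 0.247 in microglia. The labels do not say which exon was deleted, and 3′ tags from outside a deleted part would remain, so these values do not check the deletion. Xist, the RNA of the inactive X chromosome, measured 1.75 and 1019 CPM in wildtype replicates 1 and 2, and 0.950 and 1379 CPM in knockout replicates 1 and 2. The Y-linked gene Uty measured 89.4, 0.125, 81.6 and 0.0277 CPM in the same order, and Ddx3y 27.8, 0.499, 26.3 and 0.858 CPM. By these genes knockout replicate 1 has the male and knockout replicate 2 the female pattern, the opposite of the listed sex of both knockout animals. Each genotype still holds 1 library of either pattern, and replicate 1 of both genotypes has the male and replicate 2 the female pattern.

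Knockout excitatory neurons gained RNA of genes that are nearly silent in wildtype excitatory neurons, the complement gene C4b among them. Among 19059 genes tested, 574 rose and 261 fell (edgeR quasi-likelihood, adjusted p under 0.05, n = 2 per genotype), and DESeq2 and limma-voom called 848 and 853 genes. The largest effects all went up: 99 genes rose more than 8-fold and 0 fell as far, while 343 rose and 54 fell more than 2-fold. The number called was 213 with no low-count filter, 3657 with replicate number as a block, which is also a block by sex-linked RNA, and 1771 without knockout replicate 1.

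**Figure D1:**
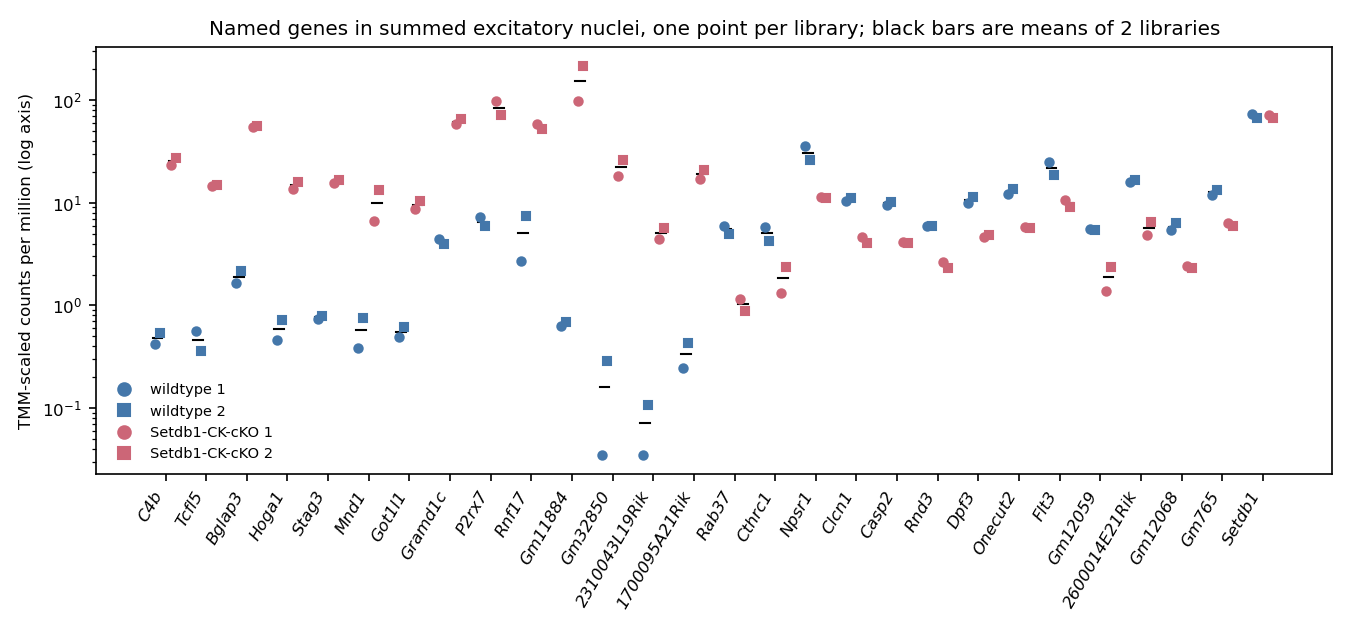
Levels of the named genes and of Setdb1 in summed excitatory nuclei, 1 point per library. C4b rose from 0.481 to 25.2 CPM and Rab37 fell from 5.49 to 1.02 CPM.

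C4b, which encodes complement component 4, rose by 5.70 ± 0.199 log2 units, from 0.481 to 25.2 CPM (edgeR adjusted p = 2.1e-06). Bglap3, an osteocalcin-related gene, rose from 1.91 to 55.3 CPM (4.86 ± 0.149). Tcfl5 (4.97 ± 0.209, 0.461 to 14.6 CPM), the meiotic cohesin gene Stag3 (4.37 ± 0.174, 0.765 to 15.9 CPM), the meiotic recombination gene Mnd1 (4.11 ± 0.417, 0.572 to 9.93 CPM) and Rnf17 (3.45 ± 0.328, 5.05 to 55.2 CPM) rose as well. P2rx7, an ATP-gated ion channel gene, rose from 6.55 to 84.2 CPM (3.68 ± 0.178) and Gramd1c from 4.19 to 61.7 CPM (3.88 ± 0.134). Hoga1 (4.65 ± 0.221, 0.589 to 14.9 CPM) and Got1l1 (4.09 ± 0.223, 0.552 to 9.45 CPM) complete the 10 established genes named for the largest rises. Both knockout libraries lay above both wildtype libraries for each of these genes.

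Among genes with predicted symbols Gm11884 rose most, from 0.658 to 154 CPM (7.86 ± 0.452), with 96.7 and 212 CPM in knockout replicates 1 and 2. Gm32850 (7.07 ± 0.389), 2310043L19Rik (6.07 ± 0.399) and 1700095A21Rik (5.79 ± 0.246) rose from under 1 CPM to 22.1, 5.08 and 18.96 CPM. Of the 99 genes that rose more than 8-fold, 26 had at most 3 wildtype UMIs. Pramel1 and the olfactory receptor gene Olfr1505 had 0 wildtype UMIs and rose at least 31.5-fold and at least 31.1-fold, and Fbxw19 had 1 (ratio 121, counting interval 21.2 to 4820).

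Falls in excitatory neurons were smaller. Rab37, a small GTPase gene, fell most, from 5.49 to 1.02 CPM (log2 fold change -2.42 ± 0.228, edgeR adjusted p = 0.000693). The neuropeptide S receptor gene Npsr1 fell from 30.6 to 11.3 CPM (-1.44 ± 0.157), the chloride channel gene Clcn1 from 10.7 to 4.37 CPM (-1.29 ± 0.147) and Casp2 from 9.86 to 4.09 CPM (-1.27 ± 0.143). Cthrc1 (-1.44 ± 0.282), Rnd3 (-1.26 ± 0.171), Dpf3 (-1.17 ± 0.146), the homeobox gene Onecut2 (-1.16 ± 0.135) and the receptor tyrosine kinase gene Flt3 (-1.13 ± 0.161) fell too. Among predicted symbols Gm12059 (-1.54 ± 0.240), 2600014E21Rik (-1.53 ± 0.156), Gm12068 (-1.29 ± 0.181) and Gm765 (-1.04 ± 0.136) fell most. Tcfl5, Rab37, Clcn1, Npsr1, Flt3, 1700095A21Rik, Gm32850, 2600014E21Rik and Gm765 overlap an annotated gene on the other strand, Hoga1 one on the same strand and Gm12068 one on each, so the source of their UMIs is uncertain. Among genes named for other classes the same holds for Zfp981, Fras1, Slco1a5, Lhfp, Pde10a, Ccn2, Sp100, Nlrc5, Nhs, Auts2, Ndufaf3, Npas3, Frmd4a and Chrm3, and also for Setdb1.

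Of the machinery of histone H3 lysine 9 methylation and the HUSH complex, Atf7ip, whose protein binds SETDB1, was the 1 gene of 22 tested that passed in excitatory neurons. It rose from 68.0 to 123 CPM (0.85 ± 0.0849, edgeR adjusted p = 0.000906), 0 fell and 21 did not pass, with 1 past the threshold when adjusted over the list alone (camera adjusted p = 0.883). Of 14 germline genes, Stk31 (1.68 ± 0.160), Mael (1.65 ± 0.340), Ddx4 (1.03 ± 0.216) and Mov10l1 (0.63 ± 0.143) rose, 0 fell and 10 did not pass (7 adjusted over the list alone). For that list camera gave adjusted p = 7.0e-05, and adjusted p = 0.600 with an estimated correlation. Of 362 Zfp genes 17 rose, 3 fell and 342 did not pass (17 up and 5 down adjusted over the list alone, camera adjusted p = 0.883). Zfp541 (2.52 ± 0.146), Zfp981 (4.94 ± 0.328), Zfp808 (1.72 ± 0.123) and Zfp990 (4.63 ± 0.380) had the smallest p. Of 27 imprinted genes Mkrn3 (3.67 ± 0.452, 0.0887 to 1.18 CPM) and Rtl1 (0.50 ± 0.0945) rose, 0 fell and 25 did not pass (5 up and 2 down adjusted over the list alone, camera adjusted p = 0.309).

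The clustered protocadherins rose as a group in excitatory neurons: 26 of 52 members passed upwards, 0 passed downwards and 26 did not pass, and 49 of 52 had a positive log2 fold change, with a median of 1.05. Adjusted over the list alone 37 rose, camera gave adjusted p = 1.2e-30, and adjusted p = 0.320 with an estimated correlation. Pcdha1 rose from 1.85 to 12.2 CPM (2.71 ± 0.189), Pcdhb17 from 7.72 to 18.8 CPM (1.28 ± 0.122), Pcdhb14 from 6.04 to 16.8 CPM (1.48 ± 0.146) and Pcdhb18 from 1.47 to 5.76 CPM (1.96 ± 0.203). By cluster 4 of 11 alpha, 10 of 21 beta and 12 of 20 gamma members rose. Pcdhgc5 did not (0.07). Alpha members share 3′ exons with each other, and so do gamma members, so 3′ tags may not tell which member they come from.

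**Figure D2:**
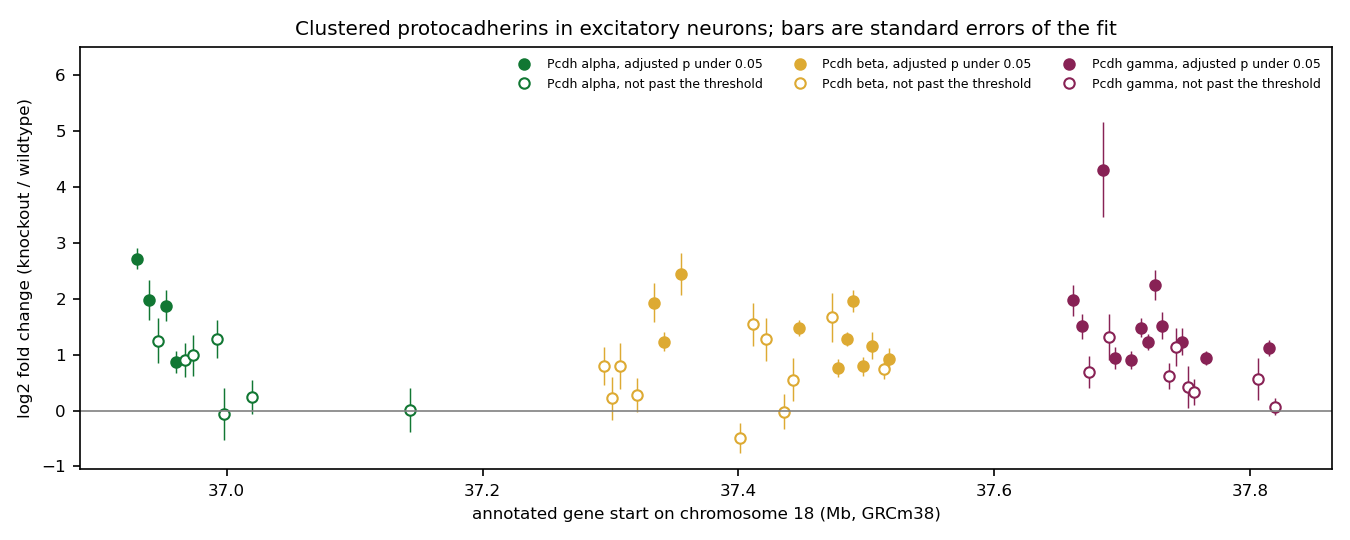
Log2 fold change of each clustered protocadherin in excitatory neurons against its annotated start on chromosome 18, with standard errors. Of 52 members 26 rose, 12 of them in the gamma cluster.

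Chromosome 18 held 38 genes that rose in excitatory neurons among 561 tested there (Fisher odds ratio 2.44, adjusted p = 7.0e-05). Without the protocadherins 12 of 509 remained (odds ratio 0.810, adjusted p = 0.741). Predicted symbols made up 202 of the 574 genes that rose, 35.2% against 22.6% of all genes tested (odds ratio 1.90, 95% interval 1.59 to 2.27). They made up 38 of the 261 that fell (odds ratio 0.579), and against a background matched on expression that odds ratio was 0.863. Of the genes that rose and matched the annotation, 376 of 573 (65.6%) were protein coding and 113 (19.7%) were lincRNA genes, against 79.1% protein coding among genes not called.

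Few genes of synapses and of neuronal activity passed in excitatory neurons, and most of those that did were lower. Of 25 activity-induced genes 0 rose and Nptx2 (-1.07 ± 0.130), Fosb (-1.44 ± 0.295) and Egr3 (-0.87 ± 0.198) fell, 22 did not pass, and 10 fell when adjusted over the list alone (camera adjusted p = 2.8e-09, and adjusted p = 0.600 with an estimated correlation). Npas4 had a log2 fold change of -0.98 ± 0.238 and did not pass (edgeR adjusted p = 0.0576). Of 26 glutamate receptor genes Grin2d rose (0.84 ± 0.136), and Grik1 (-0.64 ± 0.0783), Grm8 (-0.58 ± 0.0729), Grm4 (-0.86 ± 0.151) and Grin2a (-0.28 ± 0.0582) fell, while 21 did not pass. Adjusted over the list alone 1 rose and 8 fell (camera adjusted p = 0.0211, and adjusted p = 0.600 with an estimated correlation). For 16 GABA receptor genes camera gave adjusted p = 0.0386, and adjusted p = 0.600 with an estimated correlation.

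Of 30 postsynaptic genes Dlg2 (-0.20 ± 0.0403), Lrrtm3 (-0.35 ± 0.0706), Ppp3ca (-0.31 ± 0.0635) and Kalrn (-0.27 ± 0.0597) fell in excitatory neurons, 0 rose and 26 did not pass, with 9 adjusted over the list alone (camera adjusted p = 0.0135, and adjusted p = 0.600 with an estimated correlation). Of 29 presynaptic genes Syt2 fell (-1.10 ± 0.234) and 28 did not pass (1 adjusted over the list alone, camera adjusted p = 0.0135, and adjusted p = 0.600 with an estimated correlation). Of 28 potassium channel genes Kcnq3 (-0.35 ± 0.0636) and Kcnc2 (-0.36 ± 0.0735) fell and 26 did not pass (8 adjusted over the list alone, camera adjusted p = 0.0298, and adjusted p = 0.600 with an estimated correlation). Of 39 monoamine, stress and mood-related genes Npy1r (-0.74 ± 0.145) and Htr2a (-0.71 ± 0.143) fell and 37 did not pass (3 adjusted over the list alone, camera adjusted p = 0.150).

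Immune genes other than C4b changed in small numbers in excitatory neurons. Of 16 complement genes only C4b passed (1 adjusted over the list alone, camera adjusted p = 0.00843, and adjusted p = 0.653 with an estimated correlation). Of 35 interferon-stimulated genes Xaf1 (1.41 ± 0.236) and Ifi27l2a (2 wildtype UMIs, ratio 23.6, counting interval 6.13 to 201) rose, 0 fell and 33 did not pass. Adjusted over the list alone 7 rose (camera adjusted p = 0.00843, and adjusted p = 0.653 with an estimated correlation). Of 17 MHC genes H2-D1 (0.71 ± 0.157) and H2-K1 (1.45 ± 0.321) rose and 15 did not pass (2 adjusted over the list alone, camera adjusted p = 0.536). Of 20 inflammatory genes Casp1 fell (-2.15 ± 0.326) and 19 did not pass (1 adjusted over the list alone, camera adjusted p = 0.233), and 0 of 14 nucleic acid sensing genes passed (camera adjusted p = 0.904). Of 20 disease-associated microglia genes 0 passed (3 adjusted over the list alone, camera adjusted p = 0.0246, and adjusted p = 0.684 with an estimated correlation). Of 18 homeostatic microglia genes Cst3 rose (0.70 ± 0.148), Mef2c fell (-0.28 ± 0.0594) and 16 did not pass (2 up and 1 down adjusted over the list alone, camera adjusted p = 0.904).

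Of 21 reactive astrocyte genes Gfap rose in excitatory neurons (1.21 ± 0.274, 0.942 to 2.19 CPM) and 20 did not pass (1 adjusted over the list alone, camera adjusted p = 0.904). Of 18 astrocyte homeostasis genes Slc1a2 fell (-0.37 ± 0.0763) and 17 did not pass (1 up and 6 down adjusted over the list alone, camera adjusted p = 0.00951, and adjusted p = 0.600 with an estimated correlation). For 15 myelin genes camera gave adjusted p = 0.0933. Of 20 genes of the p53 response Sesn1 rose (0.43 ± 0.0804), Cdkn1a fell (-0.79 ± 0.163) and 18 did not pass (2 up and 2 down adjusted over the list alone, camera adjusted p = 0.233). Of 20 cholesterol synthesis genes Fdps rose (0.51 ± 0.118) and 19 did not pass (1 adjusted over the list alone, camera adjusted p = 0.904). None of 27 unfolded protein response genes and none of 13 heat shock genes passed (camera adjusted p = 0.904 for both). Of the marker lists of other cells the endothelial one stood out in excitatory neurons, where 1 of 5 members, Pecam1, rose from 3.58 to 35.2 CPM (3.30 ± 0.137, camera adjusted p = 1.0e-06, and adjusted p = 0.844 with an estimated correlation).

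Cytosolic ribosomal protein RNA was higher in knockout libraries in all 11 classes. The same 4 libraries supply every class, so the 11 classes are not independent evidence. Whether free RNA common to a library contributes was not tested. In excitatory neurons it made up 0.334% (95% interval 0.332 to 0.336) and 0.393% (0.390 to 0.395) of UMIs in wildtype, and 0.479% (0.477 to 0.482) and 0.541% (0.538 to 0.544) in knockout replicates 1 and 2. In microglia it made up 1.20% (1.17 to 1.23) and 1.36% (1.33 to 1.39) against 1.68% (1.64 to 1.71) and 1.80% (1.77 to 1.84). In excitatory neurons 32 of 75 members rose, 0 fell and 43 did not pass (67 adjusted over the list alone, camera adjusted p = 9.0e-23, and adjusted p = 0.600 with an estimated correlation), led by Rpl21 (0.56 ± 0.0913). Of 13 mitochondrially encoded genes 0 passed there (0 adjusted over the list alone, camera adjusted p = 0.00131, and adjusted p = 0.653 with an estimated correlation), and mt-Co3 had a log2 fold change of 0.66 ± 0.216. Leaving both groups of genes out gave 825 genes changed in excitatory neurons against 835.

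Some genes rose over all layers and projection types of excitatory neurons tested. Bglap3, Rnf17, P2rx7, Adk, Crlf2 and the predicted genes Gm11884, 3222401L13Rik and Gm26672 rose in all 10 excitatory subclasses or clusters tested (edgeR quasi-likelihood, n = 2 per genotype). C4b and Gramd1c rose in 9 of 9 in which they were tested, Hoga1 and Zfp541 in 8 of 8, the meiotic gene Mei1 and Atf7ip in 9 of 10, Pecam1 in 8 of 9 and the interferon receptor gene Ifnar2 in 8 of 10. In all excitatory neurons together Adk rose from 96.2 to 247 CPM (1.36 ± 0.0801) and Crlf2 from 12.7 to 43.7 CPM (1.79 ± 0.130). Tmem132d fell in 9 of 10, Auts2, Fstl4 and Npas2 in 8 of 10, and Grm8, Ptprt and Cacna2d3 in 7 of 10. Of the genes picked for the largest rises and falls in excitatory neurons, 26 of 28 tested were called in the same direction in L5 IT neurons, 20 of 28 in L2/3 IT neurons, 17 of 21 in L6 CT neurons, 20 of 24 in L4/5 IT neurons, 14 of 19 in L6 IT neurons, 15 of 22 in L5 ET neurons, 9 of 9 in L5/6 NP neurons, 7 of 7 in claustrum or L6 Car3 neurons, 15 of 27 in cluster 9 and 8 of 11 in cluster 13. These genes were picked in the pooled nuclei that include each subclass, so the counts are not independent of that choice. Protocadherins rose in some subclasses (11 of 23 tested in L6 CT, 7 of 23 in L5 IT, 6 of 27 in L2/3 IT, 5 of 14 in L6 IT, 4 of 14 in L4/5 IT, 3 of 12 in L5 ET). In cluster 9 only 1 of 22 rose, in cluster 13 0 of 3 and in claustrum or L6 Car3 neurons 0 of 1, and 0 were tested in L5/6 NP neurons. Calls summed over 14 subclasses or clusters of neuron-like nuclei, with 98 from the unnamed cluster 28, were 3063, and 1105 with DESeq2, 4835 with no low-count filter, 2020 without wildtype replicate 1 and 7170 without knockout replicate 1.

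Inhibitory neurons repeated much of the excitatory pattern with fewer genes called. Among 14432 genes 107 rose and 39 fell (edgeR quasi-likelihood, adjusted p under 0.05, n = 2 per genotype), and DESeq2 and limma-voom called 82 and 157. The number called was 1046 with replicate number as a block, 256 with listed sex as a covariate, 382 without wildtype replicate 2, 733 without knockout replicate 1 and 252 without knockout replicate 2. Bglap3 rose from 0.491 to 21.97 CPM (5.41 ± 0.430), Trim43b from 1.45 to 25.8 CPM (4.11 ± 0.330), Hoga1 from 0.608 to 10.9 CPM (4.10 ± 0.498) and Mnd1 from 1.72 to 29.6 CPM (4.10 ± 0.397). Zfp981 had 0 wildtype UMIs and rose at least 14.5-fold, and Tcfl5 had 3 (ratio 24.5, counting interval 8.02 to 122). Slco1c1, an organic anion transporter gene, fell from 6.71 to 1.75 CPM (-1.93 ± 0.391), and Unc13c fell from 137 to 73.4 CPM (-0.90 ± 0.0968). Fras1 (-0.86 ± 0.159), Osbpl3 (-0.67 ± 0.125) and Hunk (-0.65 ± 0.139) fell as well. Predicted symbols were 46 of the 107 genes that rose (odds ratio 4.18, Fisher's exact test, 95% interval 2.78 to 6.25).

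In inhibitory neurons 4 of 27 clustered protocadherins rose, Pcdhga7 (3.35 ± 0.448), Pcdhb14 (1.28 ± 0.249), Pcdha1 (1.59 ± 0.326) and Pcdhb18 (2.68 ± 0.558), with 0 falls, 23 not passed and 17 adjusted over the list alone (camera adjusted p = 1.0e-17, and adjusted p = 0.278 with an estimated correlation). Atf7ip rose from 70.4 to 117 CPM (0.73 ± 0.112), C4b from 0.611 to 9.79 CPM (3.95 ± 0.553), Zfp541 from 1.46 to 19.97 CPM (3.75 ± 0.338), Ddx4 from 2.07 to 7.78 CPM (1.89 ± 0.361), Xaf1 from 4.15 to 11.96 CPM (1.53 ± 0.322) and Sesn1 from 92.8 to 150 CPM (0.69 ± 0.101). Homer1 (-0.50 ± 0.103), Dlgap2 (-0.27 ± 0.0535), Dlg2 (-0.18 ± 0.0374), Slc4a4 (-0.48 ± 0.0950), Slc1a2 (-0.47 ± 0.101) and Csmd1 (-0.22 ± 0.0456) fell. Of 74 ribosomal protein genes 6 rose and 68 did not pass (56 adjusted over the list alone), and of 13 mitochondrially encoded genes 0 passed (7 adjusted over the list alone). Camera passed 10 of 28 lists with the preset correlation, and 0 passed with an estimated correlation or by fry.

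The response of excitatory and of inhibitory neurons overlapped far more than list sizes alone would give. Of 398 and 106 genes that rose among 14384 tested in both, 86 were shared against 2.93 expected, and of 226 and 39 that fell 17 were shared against 0.613 expected. The same 4 libraries supply both classes, which may inflate the overlap. A direct test of the difference found 140 of 18643 genes, 76 with a higher and 64 with a lower log2 fold change in excitatory neurons. That number was 248 with no low-count filter, 59 with equal nuclei of both classes and 313 without knockout replicate 1. Rab37 fell more in excitatory neurons (difference -1.84 ± 0.329, edgeR adjusted p = 0.00211), as did Flt3 (-0.76 ± 0.139). Rnf17 rose more there (1.17 ± 0.209), and Fras1 fell less (0.64 ± 0.125).

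**Figure D3:**
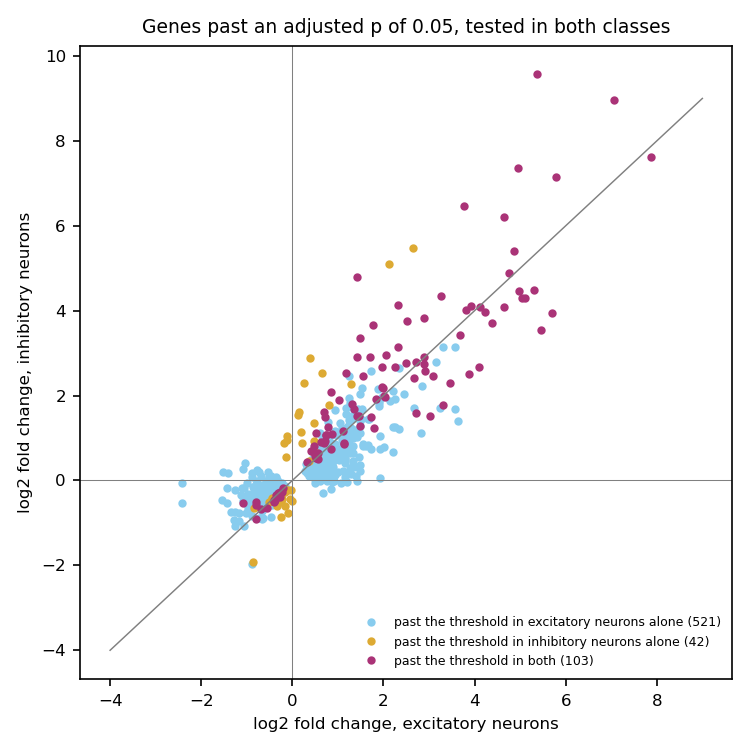
Log2 fold changes in excitatory against inhibitory neurons for genes past the threshold in either class. Of the genes that rose, 86 were shared.

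Astrocytes of knockout mice gained RNA of a small set of genes, Def8 and C4b among them. Among 12181 genes 34 rose and 3 fell (edgeR quasi-likelihood, adjusted p under 0.05, n = 2 per genotype), and DESeq2 and limma-voom called 33 and 36. Def8 rose from 16.8 to 742 CPM (5.45 ± 0.216, edgeR adjusted p = 2.0e-07), with 792 and 691 CPM in knockout replicates 1 and 2. The vomeronasal receptor gene Vmn2r78 had 0 wildtype UMIs and rose at least 63.5-fold. Slco1a5 had 2 (ratio 158, counting interval 43.1 to 1310), Tcfl5 had 2 (ratio 26.99, counting interval 6.98 to 231) and the interferon-stimulated gene Oasl2 had 1 (ratio 71.0, counting interval 12.2 to 2861). Bglap3 rose from 1.58 to 45.6 CPM (4.80 ± 0.431) and C4b from 15.4 to 72.2 CPM (2.22 ± 0.305). Lhfp fell from 255 to 100.1 CPM (-1.36 ± 0.200) and the phosphodiesterase gene Pde10a from 734 to 327 CPM (-1.17 ± 0.193). Predicted symbols were 17 of the 34 genes that rose (odds ratio 8.01, Fisher's exact test, 95% interval 3.83 to 16.7).

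The astrocytes came from cluster 12 and cluster 29, and these were mixed differently: cluster 29 held 1.91% (95% interval 1.17 to 2.93) and 3.42% (2.40 to 4.73) of wildtype and 29.6% (26.2 to 33.3) and 42.98% (39.6 to 46.4) of knockout astrocytes in replicates 1 and 2. Def8 leads the genes that set cluster 29 apart. Clusters came from the same counts as the tests, and whether cluster 29 is a separate state was not tested. The number of genes called was 103 in cluster 12 alone, an alternative added after the data were seen, 189 with no low-count filter, 414 with replicate number as a block, 66 with listed sex as a covariate, 180 with doublets kept, 22 with nuclei of at least 1000 UMIs, 147 at resolution 2.0, 325 without knockout replicate 1 and 195 without knockout replicate 2. Of 14 interferon-stimulated genes Oasl2 rose and 13 did not pass (3 adjusted over the list alone, camera adjusted p = 2.9e-05, and adjusted p = 0.517 with an estimated correlation). Of 5 complement genes C4b rose and 4 did not pass (3 adjusted over the list alone, camera adjusted p = 1.2e-05, and adjusted p = 0.517 with an estimated correlation), and the microglial genes C1qa (0.82 ± 0.282), C1qb (1.08 ± 0.290) and C1qc (0.64 ± 0.327), which did not pass, were among those 4, so microglial RNA may contribute to the list. Microglia markers as a list did not pass in astrocytes (6 members, camera adjusted p = 0.468). Of 9 reactive astrocyte genes 0 passed (3 adjusted over the list alone, camera adjusted p = 0.00121, and adjusted p = 0.517 with an estimated correlation), with Gfap at 0.98 ± 0.254 and Ggta1 at 1.62 ± 0.368. The effect differed from that in excitatory neurons for 19 of 19054 genes, 14 with a higher and 5 with a lower log2 fold change in excitatory neurons. Def8 rose more in astrocytes (difference -5.05 ± 0.223), and C4b (3.49 ± 0.399), Hoga1 (3.49 ± 0.446), Gramd1c (2.38 ± 0.375) and P2rx7 (1.90 ± 0.261) rose more in excitatory neurons. That number was 57 with no low-count filter, 141 without knockout replicate 1 and 77 without knockout replicate 2.

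Oligodendrocyte nuclei held more RNA of genes that also rose in neurons, among them Bglap3 and Rnf17, and less of single genes such as Htr2a, Egr3 and Homer1. Among 12299 genes 62 rose and 63 fell (edgeR quasi-likelihood, adjusted p under 0.05, n = 2 per genotype), and limma-voom called 145. Bglap3 rose from 2.06 to 59.5 CPM (4.79 ± 0.360), Gramd1c from 2.05 to 18.4 CPM (3.10 ± 0.451), Rnf17 from 2.05 to 16.4 CPM (2.94 ± 0.457), Pgam2 from 2.57 to 17.1 CPM (2.64 ± 0.536) and Zfp541 from 1.80 to 11.4 CPM (2.57 ± 0.567). Tcfl5 had 1 wildtype UMI (ratio 33.2, counting interval 5.39 to 1368). Relative to the gain in excitatory neurons, the gain was 0.275 for Rnf17, 0.273 for Gramd1c, 0.542 for Zfp541, 0.580 for Tcfl5 and 1.04 for Bglap3. These lay below the highest excitatory marker ratio, 1.27 for Neurod6, so free RNA from neurons could account for them. Pgam2 (4.81) lay above it, as did 21 of all 36 shared genes. Ccn2 fell from 10.3 to 1.79 CPM (-2.40 ± 0.576), the serotonin receptor gene Htr2a from 18.8 to 5.54 CPM (-1.71 ± 0.377), Egr3 from 32.1 to 12.6 CPM (-1.32 ± 0.275), Gli2 from 69.8 to 28.5 CPM (-1.24 ± 0.273), Zfand4 from 88.3 to 37.6 CPM (-1.20 ± 0.209) and Zfp804a from 38.01 to 17.3 CPM (-1.12 ± 0.239). The number of genes called was 48 with DESeq2, which left 11684 of the 12299 genes without an adjusted p, 32 with no low-count filter, 565 with replicate number as a block, 63 with listed sex as a covariate, 50 with doublets kept, 18 with nuclei of at least 1000 UMIs, 68 without wildtype replicate 1 and 382 without knockout replicate 1.

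In oligodendrocytes 3 of 20 potassium channel genes fell, Kcnq5 (-0.72 ± 0.139), Kcnh7 (-0.72 ± 0.142) and Kcnc2 (-0.81 ± 0.173), and 17 did not pass (6 adjusted over the list alone, camera adjusted p = 2.7e-05, and adjusted p = 0.518 with an estimated correlation). Of 20 activity-induced genes 2 fell, of 24 glutamate receptor genes 1, of 14 GABA receptor genes 1 and of 30 postsynaptic genes 2. Homer1 (-0.90 ± 0.152), Lrrtm4 (-0.70 ± 0.136), Csmd1 (-0.66 ± 0.127), Slc1a2 (-0.64 ± 0.135), Gabrg3 (-0.77 ± 0.180) and Grm8 (-0.84 ± 0.179) fell, and Xaf1 (1.03 ± 0.230), Cst3 (0.68 ± 0.145) and the imprinted gene Ndn (0.70 ± 0.157) rose. Of 74 ribosomal protein genes 5 rose and 69 did not pass (67 adjusted over the list alone). Markers of excitatory neurons were lower as a list (7 members, 0 passed, camera adjusted p = 0.00584, and adjusted p = 0.854 with an estimated correlation), so less RNA from neurons may contribute to these falls. The effect differed from that in excitatory neurons for 175 of 18651 genes, 116 with a higher and 59 with a lower log2 fold change there, and for 61, 58 and 83 genes without wildtype replicate 1, wildtype replicate 2 and knockout replicate 2. P2rx7 (3.13 ± 0.181) and C4b (4.39 ± 0.527) rose more in excitatory neurons, and Rab37 (-2.27 ± 0.292) and Onecut2 (-1.28 ± 0.182) fell more there. Zfand4 (difference 1.23 ± 0.192) and Zfp804a (0.998 ± 0.252) fell more in oligodendrocytes.

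In oligodendrocyte precursors 2 of 9109 genes rose and 0 fell (edgeR quasi-likelihood, n = 2 per genotype), with 646 at unadjusted p under 0.05. The 2 genes were 2310067P03Rik, with 0 wildtype UMIs and a rise of at least 16.03-fold, and Bglap3, with 1 (ratio 40.4, counting interval 6.82 to 1640). DESeq2, limma-voom, no low-count filter and the data without either knockout replicate 1 or knockout replicate 2 each gave 0 genes. There were 10 with replicate number as a block, 10 with listed sex as a covariate, 41 with doublets kept, 8 with nuclei of at least 1000 UMIs, 7 without wildtype replicate 1 and 5 without wildtype replicate 2. Npas2 (-2.06 ± 0.408), Ndufaf3 (2.20 ± 0.433) and 3222401L13Rik (1.68 ± 0.326) had the next smallest p and did not pass (edgeR adjusted p = 0.217 for each).

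Few genes changed in microglia, Nlrc5 and the interferon-stimulated gene Sp100 among those that rose. Among 8983 genes 11 rose and 7 fell (edgeR quasi-likelihood, adjusted p under 0.05, n = 2 per genotype), and limma-voom called 24. Nlrc5, whose protein activates MHC class I genes, had 1 wildtype UMI (ratio 28.2, counting interval 4.68 to 1153), and Bglap3 had 1 (ratio 55.5, counting interval 9.57 to 2230). Crlf2, a cytokine receptor gene, rose from 12.8 to 87.5 CPM (2.75 ± 0.390), Sp100 from 12.8 to 63.4 CPM (2.29 ± 0.393), the adenosine kinase gene Adk from 37.2 to 99.7 CPM (1.42 ± 0.281) and Pnmal1 from 40.4 to 102 CPM (1.33 ± 0.269). Zbtb16 fell from 113 to 36.5 CPM (-1.62 ± 0.271), Slc2a13 from 103 to 38.6 CPM (-1.41 ± 0.268) and Nhs from 154 to 58.3 CPM (-1.40 ± 0.250). Auts2 (-0.93 ± 0.179), Cntnap2 (-0.86 ± 0.172) and Kcnq5 (-0.84 ± 0.174) fell too. The number of genes called was 2 with DESeq2, 0 with no low-count filter, 293 with replicate number as a block, 0 with nuclei of at least 1000 UMIs, 35 with doublets kept and 38 with equal nuclei per library. It was 35 and 47 without wildtype replicates 1 and 2, and 0 without either knockout replicate 1 or knockout replicate 2.

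Of 13 interferon-stimulated genes in microglia Sp100 rose and 12 did not pass (7 adjusted over the list alone, camera adjusted p = 2.1e-10, and adjusted p = 0.351 with an estimated correlation), with Parp9 at 1.29 ± 0.346. Of 9 MHC genes Nlrc5 rose and 8 did not pass (3 adjusted over the list alone, camera adjusted p = 2.0e-05, and adjusted p = 0.351 with an estimated correlation), with H2-D1 at 1.47 ± 0.424 and H2-K1 at 1.10 ± 0.423. Among ribosomal protein genes Rps7 rose (0.95 ± 0.175) and 73 of 74 did not pass (33 adjusted over the list alone). The effect differed between microglia and excitatory neurons for 33 of 18627 genes, 17 with a higher and 16 with a lower log2 fold change in excitatory neurons, and for 17 and 11 genes without wildtype replicates 1 and 2. P2rx7 (difference 3.31 ± 0.197) and Hoga1 (4.21 ± 0.923) rose more in excitatory neurons, and Zbtb16 (1.37 ± 0.276) and Nhs (1.15 ± 0.269) fell more in microglia.

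**Figure D4:**
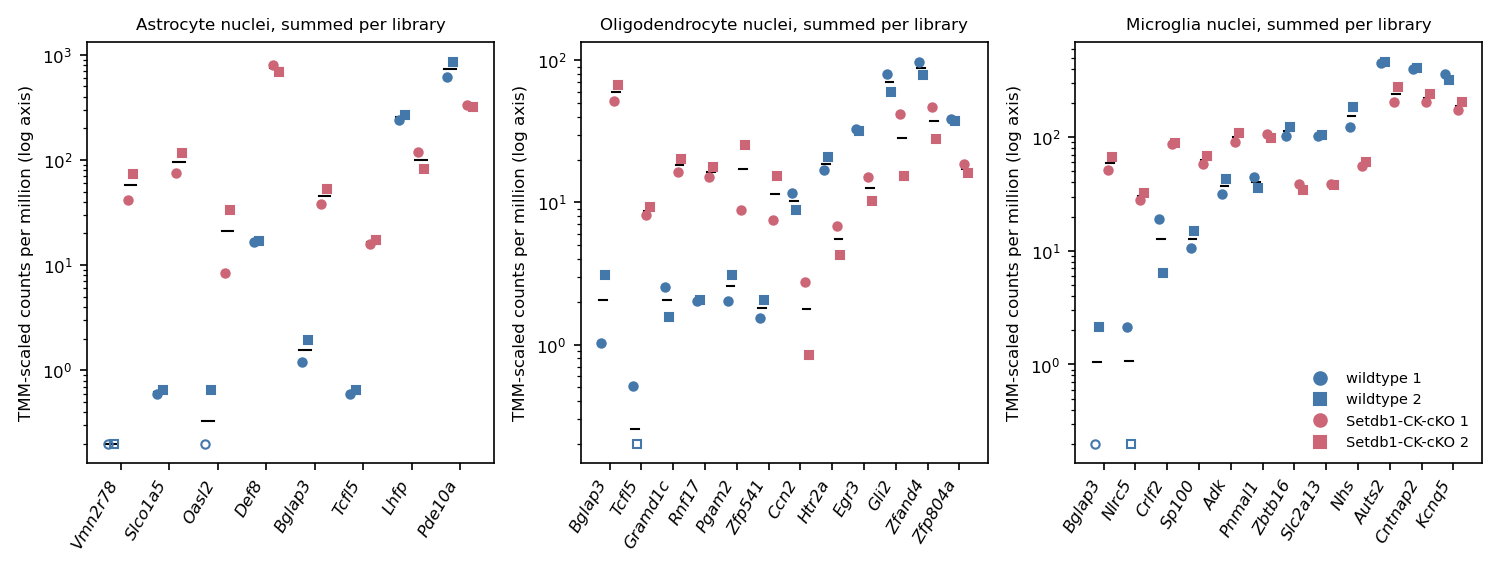
Levels of the named genes in summed astrocyte, oligodendrocyte and microglia nuclei, 1 point per library. Open points are libraries with no UMI of the gene. Def8 rose from 16.8 to 742 CPM in astrocytes.

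In the 4 smallest classes tested, each with 30 to 107 nuclei per library, 0 genes passed by edgeR quasi-likelihood. Unadjusted p was under 0.05 for 139 genes in committed oligodendrocyte precursors, 117 in endothelial cells, 124 in mural cells and 334 in fibroblasts. DESeq2 called 1 gene in mural cells and 0 in the other 3 classes, and limma-voom called 0. The 4 classes together had 94 genes with replicate number as a block, 31 with no low-count filter and 72 with equal nuclei per library. Without wildtype replicate 1, wildtype replicate 2, knockout replicate 1 and knockout replicate 2 the 4 classes together had 159, 40, 29 and 68 genes. The smallest p values belonged to Frmd4a in committed oligodendrocyte precursors (-0.93 ± 0.207, edgeR adjusted p = 0.0526), the mural marker Vtn in endothelial cells (2.54 ± 0.514, adjusted p = 0.387), Npas3 in mural cells (2.79 ± 0.469, adjusted p = 0.559) and Chrm3 in fibroblasts (-2.36 ± 0.393, adjusted p = 0.111). Mural markers were higher as a list in endothelial cells (3 members, 0 passed, 2 adjusted over the list alone, camera adjusted p = 9.1e-05, and adjusted p = 0.295 with an estimated correlation), so mural RNA may contribute to the value of Vtn. Over astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia and endothelial cells camera passed 43 lists with the preset correlation, and 0 with an estimated correlation or by fry.

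Summed over all kept nuclei, 586 genes rose and 206 fell among 20511 (edgeR quasi-likelihood, n = 2 per genotype), with 1006 by DESeq2 and 778 by limma-voom, and 674 genes changed with equal class shares. Class shares did not differ at the threshold. Microglia made up 4.62% of named nuclei in wildtype and 5.42% in knockout (log2 ratio 0.23 ± 0.0520, edgeR adjusted p = 0.0970), astrocytes 8.48% and 7.02% (-0.27 ± 0.0689, adjusted p = 0.0970), oligodendrocytes 15.7% and 12.5% (-0.33 ± 0.129, adjusted p = 0.246) and excitatory neurons 56.0% and 59.3% (0.08 ± 0.0446, adjusted p = 0.326). Inhibitory neurons made up 9.81% and 10.1%. Without knockout replicate 1 the oligodendrocyte share passed (-0.50, edgeR adjusted p = 0.000952).

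**Figure D5:**
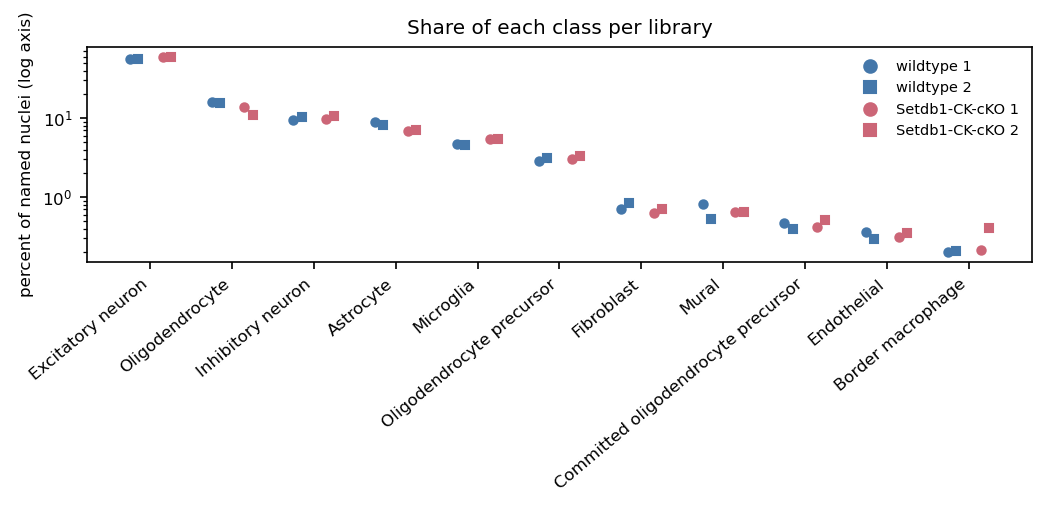
Share of each class among named nuclei, 1 point per library, on a log axis. Excitatory neurons made up 56.0% in wildtype and 59.3% in knockout.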

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

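The test of the depth of inhibitory nuclei and the test of other splits of the 4 libraries were chosen only after the results were seen.

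Many genes that rose in knockout glia also rose in excitatory neurons: 23 in astrocytes, 36 in oligodendrocytes and 7 in microglia, against 0.693, 1.33 and 0.175 expected from the sizes of the lists, and shared libraries may inflate these numbers. Free RNA from excitatory neurons in glial droplets could bring such transcripts, and so could expression in the glia. In astrocytes the median gain was 1.12 times that in excitatory neurons (95% interval 0.940 to 1.57), above the highest ratio of an excitatory marker in the knockout libraries, 0.879 for Slc17a7, as the test required. The highest marker ratio in the wildtype libraries was 1.05, within that interval. Only the 23 genes called higher in astrocytes entered, of 270 that rose in excitatory neurons and were tested in both. Genes with a small gain in astrocytes could not enter, which raises the median. The test therefore cannot tell free RNA from expression in astrocytes. The median gain ratio was 1.59 (0.776 to 2.99) in oligodendrocytes, against 1.27 for Neurod6. In microglia it was 1.01 (0.267 to 5.97) against 1.40, so in these 2 classes the explanations cannot be told apart either.

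In inhibitory neurons 86 genes rose that also rose in excitatory neurons. Free RNA, or excitatory nuclei counted as inhibitory, could give this, as could deeper sequencing of knockout nuclei or a response of inhibitory neurons themselves. The median gain was 1.02 times that in excitatory neurons (95% interval 0.882 to 1.19), above the highest excitatory marker ratio of 0.468 (0.547 in the wildtype libraries). Of the 86 genes 77 lay above 0.468, which for those genes speaks against transfer from excitatory neurons as the only source. The 86 were chosen for passing in inhibitory neurons, from 398 that rose in excitatory neurons and were tested in both. This choice raises the median, and the genes that did not pass were not examined. Median UMIs per inhibitory nucleus were 3347 and 2941 in wildtype and 3523 and 2734 in knockout replicates 1 and 2. The highest knockout minus the lowest wildtype median was 582, so the ranges overlap, and depth and a response of inhibitory neurons cannot be told apart by this test. Summed UMIs of inhibitory nuclei were 4091399 and 4212871 in wildtype, and 3563492 and 3899048 in knockout replicates 1 and 2. Both knockout sums lay below both wildtype sums, which argues against greater summed depth as the source of these rises. Which inhibitory nuclei lack Setdb1 was not analysed here.

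As a set, genes that rose in knockout astrocytes were found together in the same nuclei. In knockout replicates 1 and 2, 32.6% (29.1 to 36.3) and 42.4% (39.03 to 45.8) of astrocytes held UMIs of at least 2 of 17 such genes, and the genes were set against each other within these libraries. Finding them together could come from deeper nuclei, from doublets with neurons, or from a subset of astrocytes that changed. The summed UMIs of the other 17 genes, per UMI, were 3.63 and 2.19 times higher in those nuclei in knockout replicates 1 and 2. These ratios lay above the highest of 1000 shuffles within depth bins, 1.46 and 1.24, which speaks against depth. Excitatory markers were 1.16 and 1.31 times higher, below the lowest ratio of that sum, which speaks against doublets as the whole cause. A few abundant genes could carry the sum, and its genes were not tested singly. Cluster 29 held 170 of the 218 and 293 of the 359 nuclei with at least 2 of the first 17 genes, in knockout replicates 1 and 2. The pattern thus largely restates that cluster, which came from the same counts. In cluster 12 alone, an alternative added after the data were seen, 91 astrocyte values of genes picked for naming were the same, 16 stronger and 0 weaker. Calls among these genes were thus not confined to cluster 29. A subset of changed astrocytes may remain, and its cause was not tested.

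Effects differed from those in excitatory neurons for 140 genes in inhibitory neurons, 19 in astrocytes, 175 in oligodendrocytes and 33 in microglia. Excitatory minus inhibitory log2 fold change was -1.84 for Rab37, 1.17 for Rnf17, -0.76 for Flt3 and 0.64 for Fras1. Excitatory minus astrocyte log2 fold change was -5.05 for Def8, 3.49 for C4b, 3.49 for Hoga1, 1.90 for P2rx7 and 2.38 for Gramd1c. Excitatory minus oligodendrocyte log2 fold change was 3.13 for P2rx7, 4.39 for C4b, -2.27 for Rab37, -1.28 for Onecut2, 1.23 for Zfand4 and 0.998 for Zfp804a. Excitatory minus microglia log2 fold change was 3.31 for P2rx7, 1.37 for Zbtb16, 4.21 for Hoga1 and 1.15 for Nhs.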

How the results depend on the processing

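The alternatives of cluster 12 alone and of leaving out ribosomal protein and mitochondrially encoded genes were chosen only after the results were seen. Genes changed in excitatory neurons were 835, and 213 with no low-count filter, 3657 with a replicate block and 621 to 1771 with 1 library left out (1771 without knockout replicate 1). In inhibitory neurons they were 146, and 82 with DESeq2, 1046 with a replicate block, 256 with listed sex and 147 to 733 with 1 library left out (382 without wildtype replicate 2, 733 and 252 without knockout replicates 1 and 2). In astrocytes they were 37, and 189 with no filter, 414 with a block, 66 with listed sex, 180 with doublets kept, 22 at 1000 UMIs, 147 at resolution 2.0, 103 in cluster 12 alone and 50 to 325 with 1 library left out (325 and 195 without knockout replicates 1 and 2). In oligodendrocytes they were 125, and 48 with DESeq2 (11684 of 12299 genes left without an adjusted p), 32 with no filter, 565 with a block, 63 with listed sex, 50 with doublets kept, 18 at 1000 UMIs and 68 to 382 with 1 library left out (68 without wildtype replicate 1, 382 without knockout replicate 1). In oligodendrocyte precursors they were 2, and 0 with DESeq2, no filter or limma-voom, 10 with a block, 10 with listed sex, 41 with doublets kept, 8 at 1000 UMIs and 0 to 7 with 1 library left out (7 and 5 without wildtype replicates 1 and 2, 0 without either knockout replicate). In microglia they were 18, and 2 with DESeq2, 0 with no filter, 293 with a block, 35 with doublets kept, 0 at 1000 UMIs, 38 with equal nuclei and 0 to 47 with 1 library left out (35 and 47 without wildtype replicates 1 and 2, 0 without either knockout replicate). In the 4 smallest classes they were 0, and 1 with DESeq2, 1 with upper-quartile factors, 31 with no filter, 94 with a block, 1 at 1000 UMIs, 72 with equal nuclei and 29 to 159 with 1 library left out (159 and 40 without wildtype replicates 1 and 2, 29 and 68 without knockout replicates 1 and 2). The effect differed from that in excitatory neurons for 140 genes in inhibitory neurons (248 with no filter, 59 with equal nuclei of both classes, 106 to 313 with 1 library left out, 313 without knockout replicate 1), 19 in astrocytes (57 with no filter, 15 to 141 with 1 library left out, 141 and 77 without knockout replicates 1 and 2), 175 in oligodendrocytes (58 to 117 with 1 library left out, 61 and 58 without wildtype replicates 1 and 2, 83 without knockout replicate 2) and 33 in microglia (11 to 45 with 1 library left out, 17 and 11 without wildtype replicates 1 and 2). Calls summed over 14 subclasses or clusters of neuron-like nuclei, the unnamed cluster 28 among them, were 3063, and 1105 with DESeq2, 4835 with no filter, 9563 with a block and 2020 to 7170 with 1 library left out (2020 without wildtype replicate 1, 7170 without knockout replicate 1). Camera passed 14 lists in excitatory neurons (0 with an estimated correlation, 0 by fry, 9 to 13 with 1 library left out, 9 without knockout replicate 1), 10 in inhibitory neurons (0, 0, 5 without wildtype replicate 2 and 6 without knockout replicate 1) and 43 in the other 5 classes (0 and 0). The share of oligodendrocytes was -0.33 in log2, and -0.50 to -0.16 with 1 library left out (-0.50 without knockout replicate 1). The odds ratio of predicted symbols was 0.579 among genes lower in excitatory neurons (0.863 against a matched background), 0.143 among those lower in inhibitory neurons (0.476) and 3.06 among those higher in oligodendrocytes (2.89 with no filter). Postsynaptic genes turned from lower to higher in astrocytes without knockout replicate 1 (camera adjusted p = 0.966, and 3.1e-06 to 0.966 with 1 library left out). Of 10047 alternatives of genes picked for naming 9123 were the same, 394 weaker, 530 stronger and 0 reversed, and of 536 alternatives of lists 327 were the same and 208 weaker. The labels state no litter or batch for replicate numbers, but sex-linked RNA follows them, so the block is also a block by that sex and the 2 cannot be separated. Libraries of the same number deviated together (correlation 0.597 in excitatory neurons, 0.325 in inhibitory neurons, 0.283 in astrocytes, 0.241 in oligodendrocytes and 0.157 in microglia). The cause of these moves was not tested.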

Other observations

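The comparison of the genotypes with other splits of the 4 libraries was chosen only after the result was seen. Bglap3 and 2310067P03Rik rose in all 6 classes with calls, Crlf2 and Gm11884 in 5, and Rnf17, Tcfl5, Gm20711, Gm2682 and Gm49795 in 4. C4b, P2rx7, Gramd1c, Pnmal1, Xaf1, Zfp541 and Rpl19 rose in 3, and not every class tested each gene. Cntnap2 fell in 4 of 6 classes, and Cntn4, Fam155a, Pde10a, Slc1a2 and Slc2a13 in 3. Of genes that rose in any class, 523 rose in 1 class and 84 in 2, and of genes that fell, 280 fell in 1 and 37 in 2. Shared libraries may inflate these numbers.

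In excitatory neurons the genotypes differed in 835 genes, the split by listed sex in 0 and the split by replicate number in 6, and in 0 without sex-linked genes. Only 1 of the 3 possible splits, the genotypes, had as many genes, so a share of splits under 0.05 is out of reach and this test cannot tell. In microglia the split by replicate number changed 7 genes, and 1 without sex-linked genes.

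Genes beside Setdb1 showed no excess of calls in excitatory neurons: 1 of 79 tested genes within 1 Mb on either side, C2cd4d, was called, 3 of 141 within 5 Mb and 12 of 327 within 10 Mb (odds ratio 0.829, Fisher's exact test p = 0.681). Some olfactory receptor genes rose from no wildtype UMIs in excitatory neurons: Olfr1505, Olfr1504, Olfr1330 and Olfr1501 had 0 wildtype UMIs and rose at least 31.1-fold, 17.3-fold, 13.8-fold and 8.44-fold. Olfactory receptor genes were not tested as a list, and those that did not pass were not counted. In inhibitory neurons Cdkn2a had 2 wildtype UMIs (ratio 18.4, counting interval 4.70 to 158).

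Unnamed clusters held 14.6% (14.03 to 15.2) and 8.10% (7.65 to 8.57) of wildtype nuclei and 13.4% (12.7 to 14.01) and 10.5% (10.0 to 11.1) of knockout nuclei in replicates 1 and 2. Cluster 11, led by Pbx3 and Meis2, held 534, 286, 935 and 445 nuclei, and cluster 16, led by housekeeping genes, held 1083, 342, 261 and 528. Cluster 24, with the astrocyte markers Gpc5 and Slc1a3 among its leading genes, held 49 and 33 wildtype and 2 and 3 knockout nuclei. Left unnamed, it did not enter the astrocyte share or the astrocyte tests. Cluster 31, led by Bc1 and ribosomal protein genes, held 0 and 0 wildtype and 14 and 34 knockout nuclei. Cluster 28 held 163, 169, 117 and 136 nuclei. None of these was counted in a named class, and cluster 28 was tested on its own.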
